A study of Mus musculus with 6 samples.

How the data were processed

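RNA-seq was carried out on tdTomato-positive islet β cells sorted from 3 control and 3 βDKO samples from mice at 7 weeks of age. Per the labels' protocols, islets from tamoxifen-treated animals were dispersed, stained with DAPI and sorted by fluorescence. Control animals carried MIP-CreERT with Brg1f/+ and Brm+/-. The βDKO animals carried MIP-CreERT with Brg1f/f and Brm-/-, and both carried a Cre-activated tdTomato reporter at the Rosa26 locus. The strain background was mixed C57BL/6J and 129SV. RNA integrity was screened before library preparation, per the labels' protocols. The labels number the samples 1 to 3 within a group and do not say whether each came from a separate animal or a pool. The p-values therefore measure the spread between these samples, which may be partly technical.

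The deposited values are in TPM, a transcript abundance normalised for gene length and library total, per the file headers, with 1 column per sample and every column adding up to 1000000. TPM divides each gene's reads by its length and scales each library to the same total, so a large change in a few abundant transcripts moves the values of all the others. FastQC, Trimmomatic, HISAT2, HTSeq, DESeq2 and the mm10 build are named in the submitters' processing notes. Their versions, their roles, the annotation, the gene lengths and the use of strand are not given in the sources used here. The table held 24421 rows, of which 6614 were at 0 in all libraries, and 27 gene names had been turned into calendar dates. No column was left without a sample.

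The design had foreseen a count table and a quasi-likelihood test of counts. Because the authors deposited TPM, the test fixed beforehand for normalised values was used in its place, and the planned edgeR and DESeq2 fits were not run. Genes with at least 5 TPM in at least 3 libraries were kept, which left 10404 genes and removed 14017. Values were analysed as log2(TPM + 1) with limma's empirical Bayes test (robust, with a mean-variance trend, two-sided), group as the single factor and Benjamini-Hochberg adjustment at 0.05. Fold changes from the fit are on the log2(value + 1) scale, which understates the change of low genes. Fold values given as ratios are ratios of group mean TPM.

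Because the insulin transcripts took very different shares of the total in the groups, each result is given on a second scale, on which the TPM were divided by median-of-ratios size factors. These factors ran from 0.639 in control 1 to 1.37 in βDKO 1. That scaling was among the alternatives written before the data were examined, whereas the decision to print it beside each result was taken after the shift had been seen. It sets the typical gene to no change, and the table holds no external standard by which to choose between the scales. In the text, a gene is said to have risen or fallen where it passed the threshold in that direction on both scales. Otherwise the scale is named.

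Depth was recovered from the low values. Values of 1 gene in different libraries stand in ratios of whole numbers when reads were counted, and a read value per library was found from which 16625 of 16625 rows above 0 in at least 2 libraries (100%) came out as whole reads, within 0.01 of a read and up to a factor common to a gene's libraries. In simulation, 16255 of 16255 rows were recovered, and 1.02% of rows made without whole reads passed by chance. The recovered totals, counted up to those common factors, were 31282056, 25388872 and 30869916 reads in controls 1 to 3 and 28890594, 27410193 and 27198939 in βDKO 1 to 3. These reads entered the limma-voom alternatives only.

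The test was checked on simulated reads drawn from the control means, at the same expected depth in every simulated library, with 200 genes changed. The spread of each gene was taken from within both groups. With so few genes changed, the typical gene was unchanged by design, which the median-of-ratios scale assumes. Without a change in hormone transcripts, the TPM scale (9252 genes tested) recovered 13.0% of 1.5-fold, 71.7% of 2-fold and 98.3% of 4-fold changes and called 0.06% of unchanged genes. With Ins1 and Ins2 reduced to 0.1 of their level (10026 genes tested), the TPM scale called 90.79% of unchanged genes, whose median log2 change was 0.74. The median-of-ratios scale called 0.04% of them and recovered 20.0%, 65.1% and 94.9% of the 1.5-, 2- and 4-fold changes.

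The genes named in the text follow a rule written before the data were examined. It takes Smarca4 and Smarca2; Ins1, Ins2, Pdx1, Mafa, Nkx6-1, Slc2a2, Ucn3, Gcg, Sst and Ppy; the 8 largest rises and 8 largest falls past the threshold with a mean of at least 5 TPM and no overlap between groups, leaving out predicted genes and clone names; and up to 4 members of each gene list by smallest adjusted p. Some genes that this rule takes are not reported here, and they stay in the fits, counts and list tests. The 27 gene lists were fixed at the same time, and 21 had the 3 tested members needed for a set test. These were compared with all other genes by camera from limma with a preset correlation of 0.01, with an estimated correlation as an alternative. Fry tested each list against no change. Both had Benjamini-Hochberg adjustment over the lists. The mitochondrially encoded genes were not analysed here. Positions are from the GENCODE vM21 annotation of GRCm38, the assembly that mm10 denotes, matched by symbol for 9990 of the 10404 tested genes. The values of genes whose exons overlap a neighbour on the opposite strand are less certain if counting ignored strand.

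Alternatives were the median-of-ratios scaling, a rescaling without 6 hormone transcripts, no filter, a filter on the mean, limma-voom with sample quality weights, a non-robust fit, the replicate number as a block, stricter thresholds, pseudocounts of 0.1 and 5, and leaving out each library. Averaging βDKO 1 with βDKO 2 and limma-voom with median-of-ratios factors were added after seeing the data. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.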

Results

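The series compared tdTomato-sorted β cells of mice labelled βDKO, whose genotype is given as a Cre-deletable Smarca4 (Brg1) and a null Smarca2 (Brm), both ATPases of the Swi/Snf chromatin remodelling complex, with sorted β cells of control mice labelled as keeping an intact allele of each. It asks which transcripts of islet β cells depend on Swi/Snf. There were 6 RNA-seq libraries, 3 control and 3 βDKO, with 25388872 to 31282056 recovered reads. Between 11763 and 12071 genes reached 1 TPM in the controls, against 12344 to 12546 in βDKO.

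The libraries separated by group along the first principal component, which held 89.1% of the variance on TPM and 81.6% after rescaling. Libraries βDKO 1 and βDKO 2 were the closest pair. Their log2 values differed with an SD of 0.16, against 0.29 to 0.45 for the other pairs within a group. They were kept as separate samples because the labels number them so, and the values do not show whether they came from separate animals. The 45S ribosomal precursor transcript Rn45s was at 4035 ± 408 TPM in controls and 1435 ± 634 TPM in βDKO (SD, n = 3 each).

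The targeted genes were examined first. Smarca4 (chromosome 9, 21616169 to 21704230, mm10) stood at 8.997, 13.5 and 12.4 TPM in controls 1 to 3 and at 10.6, 10.5 and 11.4 TPM in βDKO 1 to 3. The log2 fold change was −0.08 (SE 0.17, limma adjusted p = 0.667) on TPM and −0.86 (SE 0.11, adjusted p = 5.62e-04) after rescaling. Smarca2 (chromosome 19, 26605050 to 26778322) was at 22.7 ± 7.50 TPM in controls and 23.6 ± 1.33 TPM in βDKO (SD, n = 3), a change of 0.11 (SE 0.24, adjusted p = 0.684) on TPM and −0.71 (SE 0.17, adjusted p = 0.0101) after rescaling. Neither gene was therefore lower on the deposited scale, whereas both were lower relative to the typical gene. Each value covers a whole gene, including exons outside a deletion, so it checks the labels only in part. Exons of Smarca2 overlap a transcript on the opposite strand.

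Transcripts of both insulin genes fell in βDKO. Ins1 and Ins2 together made up 48.3%, 42.6% and 43.3% of TPM in controls 1 to 3 and 6.37%, 6.52% and 8.93% in βDKO 1 to 3. The groups did not overlap, and an exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Ins1 (chromosome 19, 52264297 to 52265476) fell 16.97-fold on TPM, with a log2 fold change of −4.11 (SE 0.16, limma adjusted p = 1.42e-06) on TPM and −4.97 after rescaling. Ins2 (chromosome 7, 142678656 to 142743381) fell 4.26-fold, with −2.10 (SE 0.13, limma adjusted p = 7.61e-06) on TPM and −2.96 after rescaling.

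**Figure D1:**
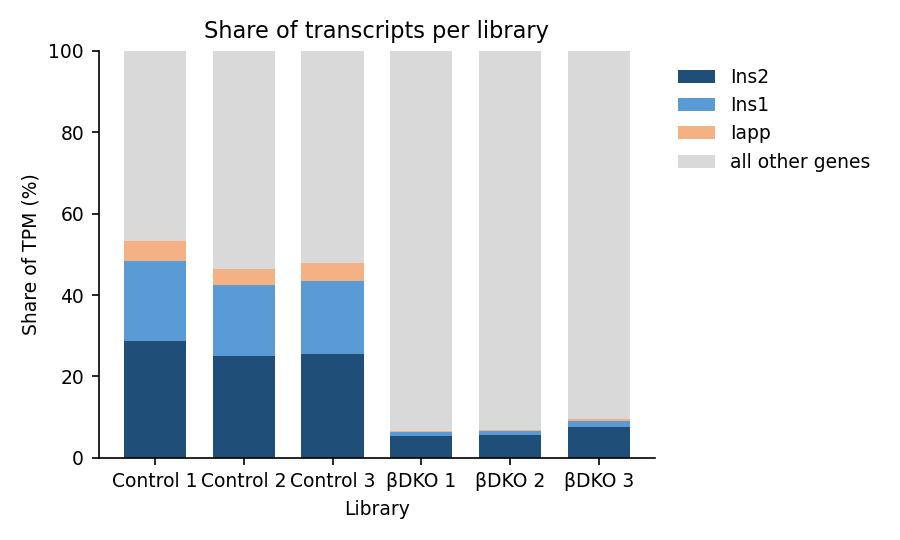
Share of TPM (%, vertical axis) taken by Ins2, Ins1, Iapp and all other genes in each of the 6 libraries (horizontal axis). Ins1 and Ins2 together take 42.6% to 48.3% in the controls and 6.37% to 8.93% in βDKO.

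This loss of insulin transcripts went with a higher TPM for most other genes. The median log2 fold change of the 10404 tested genes was 0.83 on TPM, 0.03 after median-of-ratios rescaling and 0.00 after rescaling without hormone transcripts. On TPM, 8949 genes changed, of which 8469 were higher and 480 lower (94.6% higher). After rescaling, 4627 genes changed, of which 2432 were higher and 2195 lower (52.6% higher). The 2432 and 480 genes passed in the same direction on both scales, and 653 genes were higher on TPM and lower after rescaling. Changes of at least 2-fold numbered 3702 higher and 290 lower on TPM, and 690 higher and 635 lower after rescaling. At 8-fold the numbers were 83 and 66 on TPM and 26 and 118 after rescaling. With βDKO 1 and βDKO 2 averaged into 1 sample, a choice made after seeing the data, 8397 genes changed on TPM and 3307 after rescaling.

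**Figure D2:**
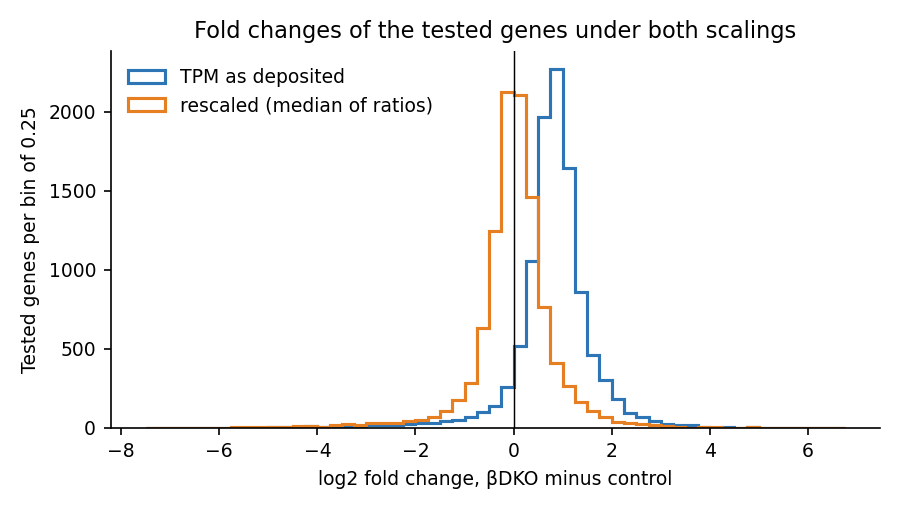
Number of tested genes (vertical axis) per 0.25 of log2 fold change, βDKO minus control (horizontal axis), on deposited TPM and after median-of-ratios rescaling. The median lies at 0.83 on TPM and at 0.03 after rescaling. Genes called with a change of at least 8-fold number 83 higher and 66 lower on TPM, and 26 higher and 118 lower after rescaling.

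The 8 largest falls included a β-cell transcription factor, a glucose transporter and receptors or channels of the β-cell membrane. They were ranked by log2 fold change from the fit and not by the ratio of means. Cox6a2, a cytochrome c oxidase subunit, fell from 264.7 ± 67.96 to 1.99 ± 1.33 TPM (SD, n = 3), a log2 fold change of −6.53. Defb1, a defensin, fell 113.9-fold (log2 −5.83). Ffar1, the receptor for long-chain fatty acids, fell from 102.6 ± 1.07 to 0.847 ± 0.114 TPM (log2 −5.81), and Trpm5, a calcium-activated cation channel, from 47.1 ± 17.01 to 0.124 ± 0.0456 TPM (log2 −5.37). Rasd1, a Ras-related GTPase, fell 42.7-fold and Kcnk16, a potassium channel of β cells, 40.8-fold. Mafa (chromosome 15, 75745490 to 75748228), a transcription factor that activates the insulin genes, fell 31.4-fold (712.3 ± 36.8 against 22.7 ± 0.895 TPM, log2 −4.91, SE 0.09, limma adjusted p = 9.43e-08). Slc2a2 (chromosome 3, 28697903 to 28731359), which encodes the main glucose transporter of mouse β cells, fell 29.5-fold (435.9 ± 104.6 against 14.8 ± 0.885 TPM, log2 −4.76). Each of these 8 genes was also lower after rescaling, by −5.58 to −7.20 on the log2 scale. Exons of Cox6a2 and Trpm5 overlap Itgad and Tssc4 on the opposite strand.

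Ranked by log2 fold change from the fit and not by the ratio of means, the 8 largest rises included a semaphorin and both subunits of soluble guanylate cyclase. Sema3c (chromosome 5, 17574281 to 17730268), a secreted guidance factor, rose from 1.86 ± 0.275 to 204.6 ± 20.7 TPM (SD, n = 3), a log2 fold change of 6.17 on TPM and 5.46 after rescaling. Basp1, a membrane-bound growth-cone protein, rose 68.0-fold. Gucy1b3 and Gucy1a3, the subunits of soluble guanylate cyclase, rose from 0.816 ± 0.0793 to 75.6 ± 4.46 TPM and from 0.288 ± 0.124 to 34.4 ± 6.43 TPM. Gpr162, an orphan receptor, rose 46.3-fold, and Tram2, a translocon-associated protein, 40.1-fold. Among abundant transcripts, Fkbp9, a prolyl isomerase of the endoplasmic reticulum, rose from 170.5 ± 29.3 to 5279 ± 1330 TPM, and Creg1, a secreted glycoprotein, from 164.5 ± 0.890 to 4490 ± 598.3 TPM. The 8 genes rose by 3.90 to 5.46 on the log2 scale after rescaling.

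**Figure D3:**
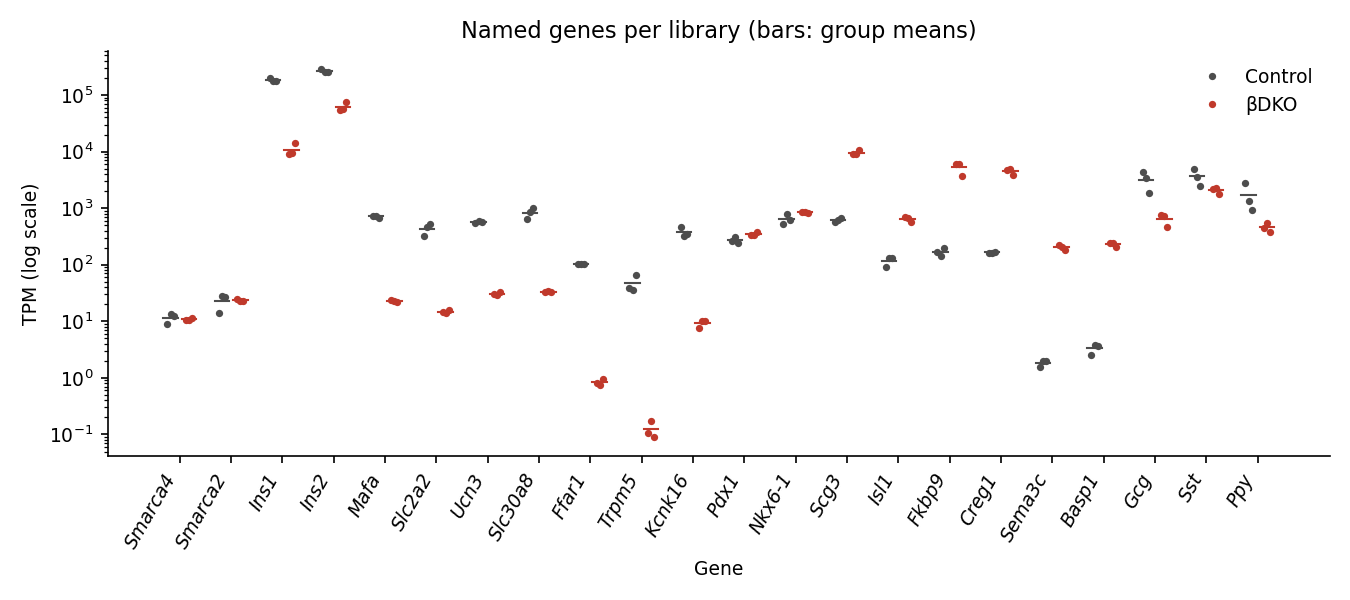
TPM (log axis, vertical) of named genes (horizontal axis) in the 3 control and 3 βDKO libraries; points are libraries and short bars are group means. Mafa falls from a mean of 712.3 to 22.7 TPM and Sema3c rises from 1.86 to 204.6 TPM, while Smarca4 has means of 11.6 and 10.8 TPM.

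Genes of hormone production and the secretory granule lay below other genes as a set, with members that rose and members that fell. Of 22 tested members, 10 were higher and 11 lower on TPM, and 7 were higher and 12 lower after rescaling; adjusted over the list alone these were 10 and 11, and 7 and 14. Ucn3, a peptide hormone of mature β cells, fell 18.8-fold (577.0 ± 21.6 against 30.7 ± 1.93 TPM, SD, n = 3), the granule zinc transporter Slc30a8 fell 25.1-fold, and G6pc2, an islet glucose-6-phosphatase, fell 5.97-fold. Scg3, a granule protein, rose 15.4-fold on TPM, to 9589 ± 1076. Camera from limma placed the list below other genes (adjusted p = 5.4e-13 on TPM, 0.020 after rescaling, and 0.020 with an estimated correlation).

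Of 30 tested genes of glucose sensing and insulin secretion, 16 were higher and 12 lower on TPM, and 7 were higher and 14 lower after rescaling (8 and 14 adjusted over the list alone). Slc2a2, Slc30a8, Ffar1 and Trpm5 led the list. The median log2 change on TPM was 0.63 and the mean −0.43, and camera gave a lower list (adjusted p = 4.7e-11 on TPM and 0.0041 after rescaling), which was lost on TPM at adjusted p = 0.27 with an estimated correlation.

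Islet transcription factors went both ways. On TPM, 15 of 23 tested members were higher and 3 lower, and after rescaling 8 were higher and 10 lower, counts that were the same adjusted over the list alone. Isl1 rose 5.46-fold, Rfx6 5.71-fold and Foxa2 3.07-fold on TPM, whereas Mafa fell 31.4-fold. Pdx1 (275.4 against 348.7 TPM) and Nkx6-1 (640.5 against 846.5 TPM), factors that maintain β-cell identity, were higher on TPM by 0.34 and 0.42 and lower after rescaling by values of −0.51 and −0.43 on the log2 scale. On TPM, Nkx6-1 lost its limma call without control 1, control 3 or βDKO 1 (adjusted p = 0.0651, 0.0614 and 0.0546) and with βDKO 1 and βDKO 2 averaged (0.0531), and Pdx1 without control 3 (0.0524). The list did not pass camera (adjusted p = 0.065 on TPM and 0.83 after rescaling), except on TPM without control 1 (0.048).

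Among 22 tested Swi/Snf subunits other than the targeted ATPases, 21 were higher on TPM, and 9 were higher and 1 lower after rescaling. Smarcd3 rose from 0.681 ± 0.318 to 12.9 ± 1.94 TPM (SD, n = 3) and Actl6b, a subunit of the neuronal form of the complex, rose from 29.5 ± 1.82 to 111.2 ± 9.16 TPM. Bcl7c rose 2.54-fold, while Bcl7b had log2 changes of 1.02 on TPM and 0.18 (adjusted p = 0.202) after rescaling. Camera gave adjusted p = 0.065 on TPM, 0.13 after rescaling and, on TPM without control 1, 0.044.

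Transcripts of other islet endocrine cells fell with the insulin genes. Gcg fell from 3198 ± 1247 to 647 ± 159.0 TPM (4.94-fold), Ppy from 1680 ± 956 to 458 ± 81.9 TPM (3.67-fold) and Sst from 3664 ± 1249 to 2072 ± 289 TPM (1.77-fold; SD, n = 3 each). Of 7 tested α-cell markers, 5 were lower and 1 higher on TPM, and 6 were lower and 1 higher after rescaling (camera adjusted p = 1e-09 and 0.018, and 0.020 with an estimated correlation). Ttr fell 7.08-fold, while Smarca1, an ATPase of the ISWI remodelling family, rose 7.01-fold. Of 3 δ-cell markers, Sst fell and Rbp4 rose 3.65-fold (camera adjusted p = 0.064 on TPM, 0.82 after rescaling, and 0.025 and 0.047 on TPM without control 3 or βDKO 2). On TPM, Sst lost its limma call without βDKO 3 (adjusted p = 0.0685). Both tested markers of PP and ε cells, Ppy and Pyy, fell. Ttr and Rbp4 are expressed beyond the cell types whose lists they stand in.

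Of 18 fixed immune-cell markers, 3 passed the expression filter, and these 3 fell. C1qa fell from 130.8 ± 41.6 to 5.79 ± 1.66 TPM, Fcer1g from 18.1 ± 2.29 to 0.386 ± 0.0788 TPM and Cd79a from 10.8 ± 3.99 to 0.478 ± 0.140 TPM (SD, n = 3 each). Camera gave adjusted p = 3e-11 on TPM, 0.0021 after rescaling and 0.020 with an estimated correlation. That call rests on these 3 genes, and Fcer1g and Cd79a passed the filter only through their control values. The other markers, and the question whether these 3 follow immune cells, are taken up under Other observations. None of 11 acinar-cell markers passed limma on either scale. Their median log2 change was 0.02 on TPM and their mean −0.09, with camera lower at adjusted p = 1e-05 on TPM, 0.44 with an estimated correlation and 0.53 after rescaling. Control 1 carried most of the acinar transcripts of its group, with the highest value of the 6 libraries for each of 23 acinar markers measured with or without the filter. Pnlip, for example, was at 68.3, 5.67 and 1.37 TPM in controls 1 to 3 and at 11.2, 8.90 and 2.22 TPM in βDKO 1 to 3. Without control 1, camera still placed the list lower on TPM (adjusted p = 0.048), though Pnlip and Cpb1 then had log2 changes of 0.88 and 0.62. Camera compares a list with other genes, most of which were higher on TPM, so its call does not show a fall of acinar transcripts. Of the ductal markers, Krt7 fell 1.47-fold, and Esam, the only 1 of 13 endothelial markers past the filter, rose 3.51-fold, each on TPM. No stellate-cell or fibroblast marker passed the expression filter. Of 3 Schwann-cell and neuronal markers, Tubb3 fell 1.75-fold and Elavl4 rose 2.62-fold on TPM (camera adjusted p = 0.033, 0.27 with an estimated correlation and 0.53 after rescaling, and 0.065 and 0.060 on TPM without control 1 or βDKO 1).

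**Figure D4:**
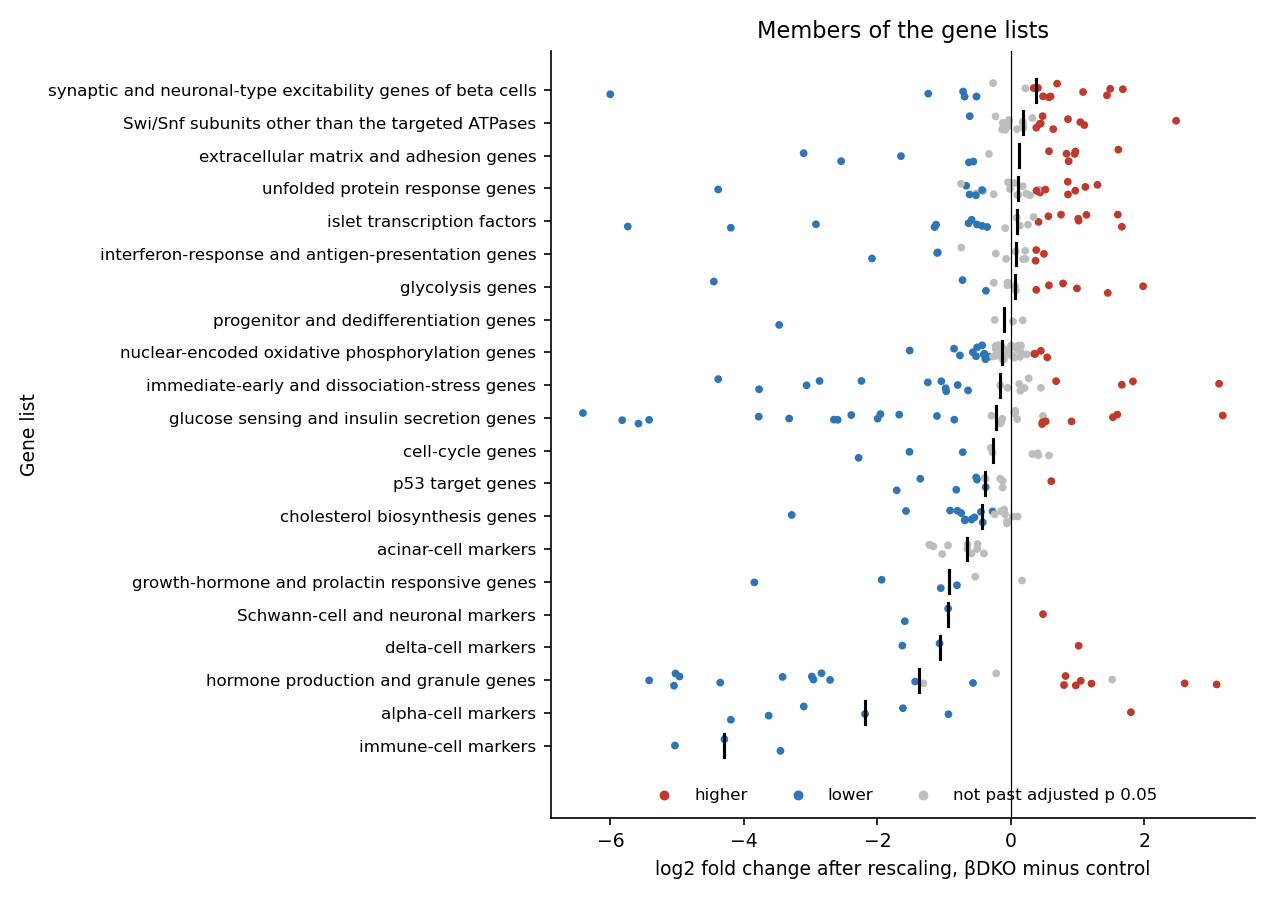
Log2 fold change after rescaling, βDKO minus control (horizontal axis), of each tested member of the 21 lists with a set test (vertical axis). Points are genes, coloured by direction where the limma adjusted p passed 0.05, and black bars are medians; the immune-cell, α-cell and hormone and granule lists have medians of −4.29, −2.18 and −1.37.

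Cholesterol biosynthesis genes were lower relative to the typical gene. Of 20 tested members, 9 were higher and 2 lower on TPM, and none was higher and 12 lower after rescaling. Sqle, which encodes squalene epoxidase, fell 1.67-fold on TPM. Nsdhl had a log2 change of 0.90 on TPM and 0.10 after rescaling. The median log2 change was 0.35 on TPM and −0.43 after rescaling (camera adjusted p = 0.0069 and 0.0021), and the call on TPM was lost at adjusted p = 0.61 with an estimated correlation and at 0.056 without control 2.

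Genes responsive to growth hormone and prolactin bear on the MIP-CreERT transgene, which is known to carry a growth hormone sequence and which both groups held. Of 6 tested members, 1 was higher and 2 lower on TPM, and 4 were lower after rescaling. Tph1, tryptophan hydroxylase, fell from 45.0 ± 30.6 to 4.64 ± 4.66 TPM and the prolactin receptor Prlr from 113.2 ± 32.5 to 50.9 ± 4.60 TPM (SD, n = 3). Camera gave adjusted p = 7e-05 on TPM, 0.026 after rescaling and 0.27 with an estimated correlation. Of 12 tested p53 targets, 7 were higher and 2 lower on TPM, and 1 was higher and 6 lower after rescaling (camera adjusted p = 0.033 and 0.036, and 0.53 with an estimated correlation). On TPM the call was lost without control 2 (adjusted p = 0.068) or βDKO 3 (0.078). The cell-cycle inhibitor Cdkn1a fell 1.97-fold and Sesn1 rose 2.76-fold on TPM.

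Of 23 immediate-early and dissociation-stress genes, 11 were higher and 6 lower on TPM, and 4 were higher and 11 lower after rescaling. The orphan nuclear receptors Nr4a2 and Nr4a1 rose 17.03-fold and 6.36-fold, whereas Atf3 fell 14.1-fold, all on TPM. Camera gave a lower list on TPM (adjusted p = 4.7e-05) that did not pass after rescaling (0.16) or with an estimated correlation (adjusted p = 0.27). Of 46 nuclear genes of oxidative phosphorylation, 43 were higher and 1 lower on TPM, and 4 were higher and 11 lower after rescaling. Camera placed them higher on TPM (adjusted p = 0.032), an outcome that did not hold after rescaling (lower, adjusted p = 0.13) or with an estimated correlation (adjusted p = 0.63), nor on TPM without control 1 (0.079) or control 3 (0.083). Ndufa1 rose 2.64-fold on TPM.

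The remaining lists did not pass camera on either scale. Of 28 unfolded protein response genes, 23 were higher and 1 lower on TPM and 9 were higher and 5 lower after rescaling, with the disulfide isomerase Pdia3 rising from 924.3 ± 30.0 to 3030 ± 231 TPM (SD, n = 3). Of 14 glycolysis genes the counts were 12 and 1, and 6 and 3. Ldhb rose 7.25-fold and Eno2 5.07-fold on TPM. Of 18 synaptic and excitability genes, 11 were higher and 2 lower on TPM and 10 were higher and 5 lower after rescaling. Of 12 extracellular matrix and adhesion genes the counts were 7 and 3, and 6 and 5, with Vcl up 5.94-fold and the collagen gene Col4a1 down 4.24-fold. Of 13 interferon-response and antigen-presentation genes the counts were 9 and 1, and 3 and 3, with Usp18 down 2.48-fold. Of 9 cell-cycle genes the counts were 5 and 2, and 0 and 3, with Cdc20 down 4.73-fold. Of 4 progenitor and dedifferentiation genes, Notch1 fell 18.9-fold, and Hes1 and Sox4 were higher on TPM and did not pass after rescaling. Of 23 fixed β-cell disallowed genes, those normally kept low in β cells, 2 passed the expression filter and were tested. Oat rose 10.4-fold, and Cat was higher on TPM only. Among the untested members, Ldha was at 0.202 ± 0.117 TPM in controls and 0.0315 ± 0.0546 TPM in βDKO (SD, n = 3). Slc16a1 was at 0.0469 ± 0.0261 and 0.0146 ± 0.0254 TPM. The 2 tested genes therefore do not stand for the list. Adjusted over the list alone, after rescaling, the counts of higher and lower genes became 10 and 6 for the unfolded protein response, 3 and 11 for oxidative phosphorylation, 3 and 4 for interferon response, 0 and 5 for growth hormone and prolactin response, 6 and 6 for matrix and adhesion, and 10 and 6 for synaptic genes. On TPM they became 4 and 2 for the cell cycle, and every other count of the lists with a set test was the same as over all genes.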

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

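Averaging βDKO 1 with βDKO 2 and limma-voom with median-of-ratios factors were chosen after seeing the data, and the planned edgeR and DESeq2 fits were not run. Changed, higher and lower genes numbered 4627, 2432 and 2195 with median-of-ratios factors, 4482, 2164 and 2318 when rescaled without hormone transcripts, 5652, 2925 and 2727 with limma-voom and median-of-ratios factors, and 4179, 3897 and 282 against a 1.5-fold change. Lower genes numbered 1098 without a filter, which tests more genes, and 1096 with limma-voom and quality weights. The other settings left the 3 counts within 1.5 times. Leaving out 1 library gave 8301 to 9002 changed genes on TPM and 3226 to 4944 after rescaling.

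Signs reversed for some genes under other scalings. With median-of-ratios factors, without hormone transcripts and with limma-voom and median-of-ratios factors, the log2 changes were −0.71, −0.75 and −0.85 for Smarca2, −0.51, −0.54 and −0.54 for Pdx1, −0.43, −0.46 and −0.47 for Nkx6-1, −0.06, −0.09 and −0.04 for Sc5d, and −0.12, −0.15 and −0.20 for Mdm2. Btg2 had −0.16 and −0.19 under the first pair. With limma-voom and quality weights, on reads and without median-of-ratios factors, both targeted genes were called lower, Smarca4 at −0.61 (adjusted p = 1.80e-04) and Smarca2 at −0.44 (adjusted p = 0.00655), and Pdx1 had −0.12, Nkx6-1 −0.06, Cpb1 0.66 and Pnlip 0.56, and with limma-voom and median-of-ratios factors Cpb1 had 0.22 and Pnlip 0.12. Leaving out 1 library gave −0.24 to 0.03 for Smarca4, −0.19 to 0.27 for Smarca2, −1.45 to 0.62 for Cpb1 and −1.56 to 0.88 for Pnlip. Cpb1 and Pnlip turned positive without control 1 (0.62 and 0.88), which alone among the controls held high values (Cpb1 at 28.4 against 2.93 and 0.680 TPM), and without βDKO 3 (0.23 and 0.09), which held the lowest of its group.

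Of the list tests, camera run on TPM with an estimated correlation lost the calls for secretion (adjusted p = 0.27), acinar (0.44), Schwann-cell (0.27) and immediate-early genes (0.27). It also lost those for oxidative phosphorylation (0.63), cholesterol (0.61), p53 (0.53) and growth hormone and prolactin genes (0.27). For the Schwann-cell list the estimate was −0.041, below the preset 0.01, so a higher correlation was not what ended that call. The hormone and granule, α-cell and immune lists also had estimates below the preset (−0.018, −0.097 and −0.153). Their camera adjusted p still rose from 5.4e-13, 1e-09 and 3e-11 to 0.020. The rise in p with this setting can therefore not be read as an effect of correlation alone. After rescaling, camera gave 0.53 for acinar, 0.53 for Schwann-cell and 0.16 for immediate-early genes, and the opposite direction for oxidative phosphorylation (0.13), matrix (0.92) and synaptic genes (0.53). Fry compares a list with no change and not with other genes, so on TPM it also picks up the median gene's rise of 0.83. On TPM fry gave adjusted p = 0.0014 for Swi/Snf, 0.0013 for unfolded protein response and 0.0011 for glycolysis genes. For acinar and growth hormone genes it gave 0.96 and 0.32. After rescaling the fry values of these lists were, in the same order, 0.001, 0.4, 0.053, 0.65 and 0.0034, the last 2 in the lower direction. On TPM its direction was higher, against camera's lower, for transcription factors (0.057), δ-cell (0.019), Schwann-cell (0.038), cell-cycle (0.0062) and immediate-early genes (0.011). The same held for cholesterol (0.11), interferon (0.0027), p53 (0.057), matrix (0.0084) and synaptic genes (0.0030). After rescaling, fry was lower for transcription factors (0.057), Schwann-cell (0.12), cell-cycle (0.11), immediate-early (0.11), cholesterol (0.0075), interferon (0.18) and p53 genes (0.013). It stayed higher for δ-cell (0.38), matrix (0.34) and synaptic genes (0.036). Leaving out 1 library, camera's adjusted p ran from 0.044 to 0.094 for Swi/Snf, 0.048 to 0.12 for transcription factors, 0.025 to 0.12 for δ-cell, 0.0084 to 0.065 for Schwann-cell, 0.020 to 0.083 for oxidative phosphorylation, 5.7e-04 to 0.056 for cholesterol and 0.0099 to 0.078 for p53 genes. The cause of these losses was not tested.

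The replicate numbers gave no sign of pairing. Same-numbered deviations correlated at −0.063, −0.026 and 0.207, within the range of −0.257 to 0.243 for differently numbered ones. With 3 samples per group, these values cannot show that the samples were unpaired. With the replicate number as a block, 8838 genes changed on TPM and 4254 after rescaling, the δ-cell list passed camera (adjusted p = 0.031), and no other call changed among the named genes and lists. At this depth the limits are the 3 samples per group and the scale, since the table alone does not fix how much RNA a cell held.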

Other observations

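The tests of the RNA content, the targeted genes and the cell-type markers, the gene families and the cell-cycle genes were chosen after the results had been seen, whereas those of hormone share, neighbouring genes and sample splits were not.

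Over the whole fixed list of cell-cycle genes, whether or not they passed the expression filter, 17 of 28 had every βDKO library below every control library on TPM and 6 had every one above, against 7.7% and 59.2% of the other genes with a value above 0. After rescaling the numbers were 19 and 1, against 24.2% and 23.7%. Of the 9 members that passed the filter, limma called 5 higher and 2 lower on TPM. Mki67, a marker of cycling cells, was at 2.58 ± 0.386 TPM in controls and 0.0823 ± 0.0246 TPM in βDKO, and Top2a, a topoisomerase of dividing cells, at 4.03 ± 1.38 and 0.196 ± 0.0662 TPM (SD, n = 3 each). Immune-cell markers fell alongside, 12 of 16 of them below every control on TPM, and which cells the cell-cycle transcripts came from was not tested.

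Ribosomal protein genes rose as a family, with 46 of 78 higher and 3 lower after rescaling (median log2 change 0.39; Fisher's exact test, two-sided, adjusted p = 2.9e-10 over 20 tests of families). Semaphorins and plexins had 7 of 12 higher (adjusted p = 0.065) and potassium channels 9 of 20 lower (adjusted p = 0.091), neither past the threshold. Ribosomal protein genes have many near-identical pseudogene copies, so their values are uncertain, and the test treats genes as independent, which they are not.

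Most genes had a higher TPM in βDKO, and 8949 genes were called. Of the 10 splits of the 6 samples, 1, the real one, gave as many; limma called 0 genes in each of the other 9, with 4 to 53 at an unadjusted p under 0.05, and 10 splits are too few for a share under 0.05. Rescaling without hormone transcripts brought the median log2 change from 0.833 to 0.001, so the share taken by insulin and other hormones may account for the shift in the typical gene. More RNA per βDKO cell stays open and cannot be told apart from it, because both leave the median of 0.833 and the table holds no external standard.

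Smarca4 and Smarca2 were not lower on TPM. After rescaling with median-of-ratios factors, 2 of 2 genes had every βDKO library below every control library (log2 changes of −0.86 and −0.71). Limma-voom with quality weights on the recovered reads called both lower (−0.61 and −0.44). That fit scales to total reads, which is a further change of scale. It also moved Pdx1 and Nkx6-1 down, from 0.34 and 0.42 on TPM to −0.12 and −0.06, so it is not separate evidence of a loss. The rescaled scale lowers the median gene from 0.833 to 0.028, so genes with a TPM change near 0 were bound to come out lower, and whether the scaling of TPM to a fixed total hid a loss of these transcripts stays open. A single wrongly labelled βDKO library is argued against, as 0 of the 3 had Mafa or Slc2a2 within the control range. Reads from exons outside the deletions could also keep the values up, which stays open because 0 of the 2 genes have values per exon here.

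Markers of several other pancreatic cells were lower in βDKO, with medians of the rescaled log2 ratio from −4.22 for immune cells to 0.94 for 3 endothelial markers, a range of 5.16. Every βDKO library was below every control after rescaling for 14 of 16 immune, 8 of 9 α-cell, 3 of 5 δ-cell, 4 of 10 ductal, 1 of 23 acinar and 0 of 3 endothelial markers. The acinar median of −2.10 came from control 1 and was 0.49 without it. Fewer cells of all other types after the tdTomato sort cannot be told apart from separate changes. The endothelial markers spread from −2.61 to 2.94, a spread added to the bound after a first run in which their median alone had met it. The −2.61 was Plvap, which rests on control 1, at 3.06, 0 and 0 TPM in controls 1 to 3 and 0.139, 0.428 and 0.145 TPM in βDKO 1 to 3. The other 2, Esam and Egfl7, had every βDKO library above every control after rescaling, and 2 markers are too few to decide. The fixed list held 13 endothelial markers, and the rest lay under the mean of 0.3 rescaled TPM needed here. Among them, Pecam1 was at 0.0819 ± 0.0614 TPM in controls and 0.0368 ± 0.0215 TPM in βDKO (SD, n = 3). Whether Esam and Egfl7 follow endothelial cells in these libraries was not tested. Gcg over Sst was 0.765 to 0.937 in controls and 0.267 to 0.352 in βDKO. For immune cells, all 16 markers were first tested as a single set (14, or 87.5%, below every control after rescaling and 12 on TPM), and were divided once C1qa, Fcer1g and Cd79a had been seen to differ. Of the other 13 markers, 84.6% were below every control after rescaling and 69.2% on TPM, so the bound set for them (0.75) was met on the rescaled values, to which a first run was limited, and missed on TPM, and fewer immune cells stays open for them. For C1qa, Fcer1g and Cd79a, fewer immune cells as the whole source is argued against by the levels of their partners. Partners here are genes that immune cells express alongside these 3. In controls 1 to 3, C1qa was at 86.5, 136.7 and 169.2 TPM against 1.52, 13.8 and 2.42 for C1qb, another subunit of the same protein; Fcer1g was at 20.2, 18.5 and 15.6 TPM against 0, 5.41 and 1.08 for Tyrobp; and Cd79a was at 6.44, 14.3 and 11.7 TPM with Cd79b at most at 0.0690 and Ms4a1 at 0. In the median control each of the 3 lay at least 14.5 times above its highest partner, and in control 2 C1qa and Fcer1g lay 9.9 and 3.4 times above. For Fcer1g the 14.5 was control 3, and control 1 counted as above it because Tyrobp was at 0 there. The argument is therefore weakest for Fcer1g. The bound for these 3 genes was written with the values in view. An effect of the genotype on these transcripts was not tested.

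A further hypothesis, that genes carried along with the targeted alleles on the mixed background changed more often, was not borne out: within 10 Mb, 42.7% of tested genes around Smarca4 and 47.2% around Smarca2 were called after rescaling, at most the 69.9th percentile of windows around random tested genes.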
